A study of Homo sapiens with 12 samples.

How the data were processed

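EndoC-βH1 cells, a human pancreatic beta-cell line, were left untreated or given 1000 U/ml of interferon gamma (IFNγ) and 2 ng/ml of interleukin 1 beta (IL1β) for 24 h. Each condition had 3 libraries in each of 2 assays. For ribosome profiling, cells received 2 µg/ml of harringtonine for 30 min, which holds ribosomes at start codons, and 100 µg/ml of cycloheximide for 30 s, which stops elongation. For the other assay, polyadenylated RNA was read directly on nanopore flow cells, 1 read per RNA molecule. No library is shared between the assays, and cells of one assay were not matched to cells of the other.

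The deposited footprint files, 1 per condition, hold counts of footprints per position of an Ensembl transcript, placed by the ribosomal P site at 12 nt from the 5′ end of footprints of 26 to 30 nt. The authors' raw counts are whole numbers and are not scaled. A position is listed for a condition where it has 4 or more counts over the 3 libraries and a count in 2 or more of them, as tested on the values. A footprint that matches several transcripts is counted on each, so totals are sums over listed positions rather than numbers of molecules. The files also carry a deposited mark for positions that the authors called peaks, by a rule that was not stated. The deposited long-read table holds raw counts per transcript model for 17401 models of 8163 genes, with novelty classes from the authors' long-read annotation tool, and lists models whose mean count in the higher group is 10 or more. The means of the authors equal the means of the columns assigned to each group, with a largest difference of 0. The submitters' notes name cutadapt 2.8, STAR 2.7.3a, minimap2 2.17 and the GRCh38 build without saying which step used them.

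Footprint transcripts carry no gene name. The long-read table pairs 5908 known Ensembl transcripts with a gene, and these pairs gave a gene to 4354 of the 35652 footprint transcripts. Gene sums used the 3670 named transcripts listed in both conditions (2896 genes), with a position missing from one table counted as 0. That choice was made after the data were examined, to keep out transcripts listed in one condition alone; a sum over every named transcript gave 149 calls, some of them genes whose fold change did not move, such as UQCRFS1 (log2 -2.59 in both), and the cause of the larger count was not tested. The value of each choice is in the closing section. A missing position can hold fewer than 4 counts, or any number of counts in a single library. Footprint fold changes were therefore also computed with 1 count per library at missing positions, which is not a bound. Values of this kind are given for some genes only. Coordinates are those of the RefSeq annotation of GRCh38.

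Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10), and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The model for footprints had a term for the flow cell named in the labels, 4 libraries on one and 2 on the other, each with libraries of both conditions. Transcript usage within a gene was tested with diffSpliceDGE and Simes p values per gene. The footprint to long-read ratio was tested as the interaction of assay and treatment over all 12 libraries. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 5 measured genes. The rotation test fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Shares of footprint counts were compared by exact 2-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Intervals of shares are exact Clopper-Pearson intervals at a level of 0.95. Intervals and floors cover counting error only. Folds against a group with no counts use a floor of 3 counts over the group. Standard errors of log2 fold changes were computed from the F statistic. DESeq2 1.42.0, R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

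Tests, gene lists and most alternatives were chosen before the data were examined. The lists cover the interferon response, antigen presentation by class I and class II, the constitutive proteasome, NF-κB and IL1 responses, immune checkpoints, endoplasmic reticulum (ER) stress, beta-cell transcription factors, the insulin granule, stimulus-secretion coupling, islet autoantigens, other islet cells, exocrine and ductal cells, mesenchymal, endothelial and immune cells, apoptosis and pyroptosis, proliferation, ribosomal proteins, translation factors, oxidative phosphorylation, the mitochondrial genome, cholesterol synthesis, splicing regulators, immediate early genes, and loading references. Named genes follow a rule set at the same time: up to 8 called genes per direction with the largest fold change, a mean of at least 10 CPM in the higher group and complete separation of the groups, the 3 members of each list with the smallest p, and a few genes whatever their values, among them INS, IRF1, CXCL10, HLA-B and CD274. For transcripts, usage and the ratio it takes up to 5 genes per direction with the smallest p. Reads of HLA, GBP, IFIT, C4 and ribosomal protein genes can be shared between similar copies.

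Replicate numbers were tested as pairs by correlating residuals of libraries after removing the mean of their group. Same-numbered libraries gave 0.618, 0.507 and 0.132 in long reads and 0.789, 0.522 and 0.571 in footprints, and values for other pairs reached 0.192 and 0.508. Each main count is therefore given also with the replicate number as a block. No pair of libraries of one group was a duplicate (chi-square per degree of freedom 1.38 to 76.2). Alternatives were other scalings, filters and tests, flow cell or run-name terms, the replicate block, leaving out each library, and other sets of positions. Recovery was tested on simulated data: of genes changed 2-fold, 50% were called in long reads and 3.1% in footprints (61.9% with the block), and of those changed 4-fold, 96.7% and 33.3% (98.4% with the block). At single positions 0% of 4-fold changes were called, and 84.9% with the block. Values with the block come from separate simulations that used the dispersion of the block fit. No simulation held a replicate effect, so they do not measure what blocking gains on the same data. For the ratio, 25.9% of 4-fold changes were called with 13.3% false calls, and for usage 31.0% were called.

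Left out were the footprints of transcripts without a gene name, of which 20123 were tested apart for the closing section, antisense and intergenic models as groups of their own, and read sequences, which were not used here. In long reads the filter on low counts left out 574 genes, CXCL10 and HLA-B among them; their counts and the test with no filter are given in the report. CD274 had no long-read model, and neither CXCL10 nor CD274 had a named footprint transcript.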

Results

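Translation starts and full-length RNA were measured in EndoC-βH1 cells, a human beta-cell line that makes insulin, to ask which RNAs and which start codons are used when beta cells meet the inflammatory cytokines IFNγ and IL1β. Ribosome footprints after harringtonine (3 untreated and 3 cytokine libraries) and direct RNA long reads (3 and 3 other libraries) were taken after 24 h. Listed footprint counts summed to 14834302, 10072029 and 7096381 in untreated replicates 1 to 3 and to 20530701, 5972446 and 6572110 in cytokine replicates 1 to 3. Between 7.5% and 14.5% of them lay on transcripts with a gene name. Long-read counts were 991671, 790537 and 877407 in untreated and 905819, 781500 and 1177378 in cytokine replicates. The footprint tables listed 397084 positions for untreated and 370063 for cytokine-treated cells, 248409 of them in both.

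Which RNAs differ between cytokine-treated and untreated cells was asked with the long reads summed per gene. RNA of interferon-response and antigen-presentation genes rose most. WARS1 (ENSG00000140105.18, GRCh38 chromosome 14, 100333790 to 100376327), the tryptophanyl-tRNA synthetase of the cytosol, rose from 89.8 ± 13.5 to 3114 ± 64.1 CPM (mean ± SD, n = 3 per group), a log2 fold change of 5.11 (SE 0.16, adjusted p = 4.9e-10). TAP1 (ENSG00000168394.11, chromosome 6, 32845209 to 32853704), a subunit of the transporter that brings peptides to class I molecules, had no count in untreated cells and 1545 ± 488 CPM after cytokines, at least 1425-fold higher. IRF1, a transcription factor of the interferon response, rose from 8.38 ± 3.65 to 849 ± 205 CPM (log2 6.65, SE 0.28).

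Of 66 interferon-response genes 33 were measured, and all 33 rose, 33 adjusted over the list alone. Their median log2 fold change of 5.02 stayed 5.02 when the 7 genes without untreated counts were set to their lower bound. Models are listed only with a mean count of 10 or more in the higher group. A gene silent in untreated cells therefore enters only with reads after cytokines, so the 33 of 33 was partly set by the listing. Of 22 genes of class I antigen presentation 19 were measured, under the same limit, and all 19 rose as well. Adjusted over the list alone 19 passed, with a median of 3.86. Among them were PSMB10, a catalytic subunit of the immunoproteasome (log2 5.52, SE 0.18), PSME2, a subunit of the proteasome activator (4.06, SE 0.14), and HLA-E, a class I molecule read by natural killer cells (3.76, SE 0.15). Each list differed from other genes by camera (adjusted p = 1.7e-99 and 6.7e-72) and kept its call with adjusted p = 0.0051 and adjusted p = 0.025 with an estimated correlation, although the replicate block together with an estimated correlation gave adjusted p = 0.109 for each. The genes with the largest fold changes had no untreated counts and were at least 899-fold (PLAAT4), 666-fold (UBD), 438-fold (PSMB9), 318-fold (APOL1), 302-fold (GBP1), 190-fold (HLA-C) and 185-fold (APOL6) higher. UBD, a ubiquitin-like protein induced by inflammatory cytokines, had 17, 773 and 1175 counts in cytokine replicates 1 to 3, and its adjusted p went from 0.0053 to 0.0544 without untreated replicate 3.

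Several chemokines and interferon genes were missed by the filter on low counts, because cytokine replicate 1 had few of their reads. CXCL10, the chemokine that draws T cells to islets, had 0 counts in all untreated libraries and 7, 388 and 609 in cytokine replicates, at least 342-fold higher (adjusted p = 0.0079 with no filter). HLA-B had 9, 32 and 47 counts against 0, at least 30.0-fold higher (adjusted p = 0.0020). Of 574 genes below the filter, 23 were higher and 0 lower with no filter in edgeR, and 47 higher and 16 lower with the replicate block. The 23 include the chemokines CXCL9, CXCL11, CXCL1 and CX3CL1 and the inflammatory caspase CASP4, the first 2 at least 51.1-fold and 12.9-fold higher over untreated cells without reads, the others with log2 fold changes of 5.48, 3.81 and 4.78 (SE 0.93, 0.87 and 0.90).

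Of 7589 genes tested, 189 rose and 11 fell in edgeR, 216 and 9 in DESeq2, and 712 had an unadjusted p below 0.05. Every one of the 200 had its groups fully apart. Among unselected genes 10% would show this by chance with 3 against 3 libraries. Selection by p from the same libraries favours it, so the contrast is no separate evidence. The interferon and class I lists held 52 of the 189, and 113 were in no list. All 200 remained called with the replicate block, which called 473 higher and 262 lower genes. Without cytokine replicate 1 the count was 325. The run-name prefix, which sets both replicate 1 libraries apart, gave 377 higher and 144 lower genes as a term, and leaving out both replicate 1 libraries gave 303 and 63.

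Proteasome and ER stress genes rose by smaller steps. Of 14 constitutive proteasome subunits 7 rose (11 adjusted over the list alone, 11 with the block; median log2 0.52), among them PSMA4 (0.79, SE 0.12), PSMA6 (0.84, SE 0.13) and PSMA5 (0.99, SE 0.19), the last not called without untreated replicate 3 (adjusted p = 0.0915) or cytokine replicate 3 (0.0744). The list had adjusted p = 6.2e-12, and adjusted p = 0.21 with an estimated correlation. Of 24 ER stress genes 8 rose (11 adjusted over the list alone, 13 with the block; median log2 0.56): HSPA5, the main chaperone of the ER, went from 690 ± 111 to 1363 ± 190 CPM (log2 0.98, SE 0.15), HERPUD1, which helps degrade misfolded proteins, gave 1.13 (SE 0.17), and MANF, a secreted stress factor, gave 1.00 (SE 0.18; adjusted p = 0.0501 without untreated replicate 3). That list had adjusted p = 6.1e-11, and adjusted p = 0.14 with an estimated correlation. By fry both lists moved upward (adjusted p = 0.041 and 0.021), but with the block the ER stress list did not pass (adjusted p = 0.017 and 0.12).

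Of 13 apoptosis and pyroptosis genes 3 rose, 3 adjusted over the list alone: TNFSF10, the death ligand TRAIL (log2 2.58, SE 0.26), PMAIP1, a BH3-only protein that promotes apoptosis (1.03, SE 0.16), and MCL1, which opposes it (0.74, SE 0.13). The list had adjusted p = 0.010, and adjusted p = 0.17 with an estimated correlation. Of 5 measured NF-κB and IL1 genes 1 rose (2 adjusted over the list alone): NFKBIA, the inhibitor of NF-κB, with log2 2.02 (SE 0.42), which was not called without untreated replicate 2 or 3 or cytokine replicate 2 or 3 (adjusted p = 0.069 to 0.15). NFKBIZ had log2 1.40 (adjusted p = 0.13, 0.0067 with the block, and 0.034 without cytokine replicate 1). Both immune checkpoint genes rose, HLA-E and CD47, the signal against phagocytosis (1.60, SE 0.21). Of 2 class II genes, CD74, the invariant chain, rose (3.83, SE 0.51), and CTSL, a cathepsin, did not pass (0.06). Of 12 immediate early genes JUNB rose (0.74, SE 0.16; 2 genes adjusted over the list alone), but was not called without untreated replicate 1 or 3 or cytokine replicate 2 or 3 (adjusted p = 0.073 to 0.20), and FOS had 1.55 (adjusted p = 0.081, 0.0065 with the block).

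No gene of the beta-cell identity lists fell past the test, and one granule gene rose. INS (ENSG00000254647.6, chromosome 11, 2159779 to 2161209), the insulin gene, had 4407 ± 365 CPM in untreated and 3309 ± 399 CPM in cytokine-treated cells (log2 -0.41, SE 0.14, adjusted p = 0.23; adjusted p = 1.8e-05 with the block, 0.016 without both replicate 1 libraries). MAFA, a transcription factor of mature beta cells, had log2 -1.15 (SE 0.35, adjusted p = 0.15; 0.0016 with the block, 0.038 without untreated replicate 1), and NKX6-1, another, -0.30 (adjusted p = 0.62; 0.031 with the block). Of 18 beta-cell transcription factors 0 were called by edgeR or DESeq2, 0 adjusted over the list alone, and 1 had an unadjusted p below 0.05; the block called 2 lower. Of 17 granule genes SCG3, a granin of the granule membrane, rose (log2 1.11, SE 0.18), and 3 higher and 1 lower genes passed adjusted over the list alone; the block called 3 higher and 3 lower. CHGA, the precursor of islet chromogranin peptides, had 25740 ± 1038 and 43260 ± 9405 CPM (log2 0.75, SE 0.19, adjusted p = 0.056); it was called with the block (5.5e-11), with no filter (0.049), with library sizes alone (0.037), without untreated replicate 2 (0.037), without cytokine replicate 1 (0.0050) and by DESeq2 (0.00030). Of 10 islet autoantigens 0 were called by edgeR and 1 by DESeq2 (2 higher and 1 lower adjusted over the list alone, 2 and 2 at an unadjusted p below 0.05). Of 18 stimulus-secretion genes 0 were called by either tool, also adjusted over the list alone, and 1 had an unadjusted p below 0.05 (RAB27A, log2 1.21, adjusted p = 0.099; 0.0016 with the block).

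Of the markers of other cell types 1 rose, the ductal keratin KRT19. Of 4 genes of other islet cells 0 passed by edgeR or DESeq2, also adjusted over the list alone, with 0 at an unadjusted p below 0.05; glucagon (GCG) had 27.3 ± 4.53 and 19.3 ± 12.8 CPM. Of 2 exocrine and ductal genes KRT19 went from 401.7 ± 23.8 to 690.9 ± 51.4 CPM (log2 0.78, SE 0.12, adjusted p = 0.0014, 1 adjusted over the list alone), and CPA1, an acinar protease, had 0.24. None of the 13 mesenchymal, endothelial and immune markers was measured.

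The housekeeping lists had medians close to 0. Called by edgeR, by DESeq2 and adjusted over the list alone were 0 of 78 ribosomal protein genes (median log2 0.00), 0 of 45 translation factors (0.06), 0 of 49 oxidative phosphorylation genes (0.08), 0 of 12 mitochondrial genome genes (-0.04), 0 of 33 splicing regulators (-0.02) and 0 of 10 loading references (-0.02). At an unadjusted p below 0.05 these lists had 2, 1, 2, 1, 0 and 0 genes. EIF2AK2, the kinase that stops translation on double-stranded RNA, had log2 1.25 (adjusted p = 0.0509; 0.00052 with the block), and MT-CO1 had 1.08 (adjusted p = 0.14; 1.2e-15 with the block, 0.0025 without cytokine replicate 1, 0.031 without untreated replicate 3). Of 23 cholesterol genes 0 were called by edgeR or DESeq2 (1 adjusted over the list alone, 3 at an unadjusted p below 0.05, 6 higher with the block), yet the list had adjusted p = 0.024, and adjusted p = 0.79 with an estimated correlation. Its call ended without untreated replicate 2 (0.18), untreated replicate 3 (0.31) or cytokine replicate 1 (0.73). Of 24 proliferation genes 0 were called by edgeR or DESeq2, 0 adjusted over the list alone, with 4 lower at an unadjusted p below 0.05 and 8 lower with the block; the median was -0.28. That list had adjusted p = 0.00081, and adjusted p = 0.69 with an estimated correlation, and its call ended without untreated replicate 2 (0.058) or cytokine replicate 1 (0.70). Other tested lists had adjusted p of 0.070 (oxidative phosphorylation; 0.041 with the block) or more.

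The genes that fell were in none of the lists. FABP1, a fatty acid binding protein, fell from 38.2 ± 4.99 to 14.4 ± 4.02 CPM (log2 -1.43, SE 0.32), and DANCR, a long non-coding RNA that hosts a small nucleolar RNA, from 153 ± 15.1 to 59.4 ± 7.72 CPM (-1.37, SE 0.17). NKX6-3, a homeobox transcription factor (ENSG00000165066.13, chromosome 8, 41645177 to 41650817), fell from 308 ± 21.5 to 142 ± 20.4 CPM (-1.12, SE 0.15). NT5DC2 (-1.27), AC245297.1 (-1.13), NANOS1 (-1.07), EMP2 (-0.88) and GPC1 (-0.86) made up the rest of the 8 largest. The calls of FABP1, AC245297.1 and GPC1 each ended when any library other than cytokine replicate 1 was left out (adjusted p = 0.067 to 0.25, 0.057 to 0.22 and 0.092 to 0.23), and DESeq2 did not call AC245297.1 (adjusted p = 0.075) or GPC1 (0.15). EMP2 was not called without untreated replicate 2 or 3 or cytokine replicate 2 (0.069 to 0.15), nor NANOS1 without untreated or cytokine replicate 3 (0.078 and 0.099).

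**Figure D1:**
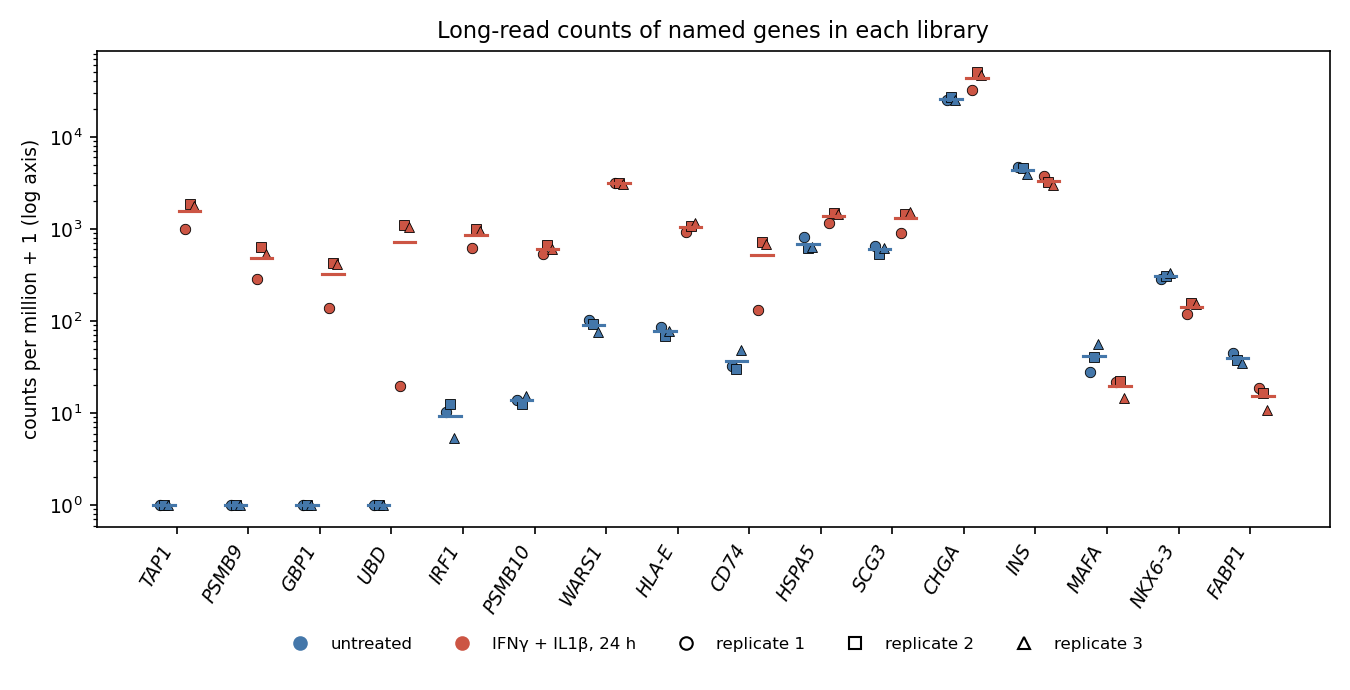
Long-read level (CPM plus 1, log axis) of 16 named genes in untreated and cytokine-treated cells, 1 dot per replicate and a line at the mean of 3. TAP1 and PSMB9 have no untreated reads, while INS sits at 4407 and 3309 CPM.

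**Figure D2:**
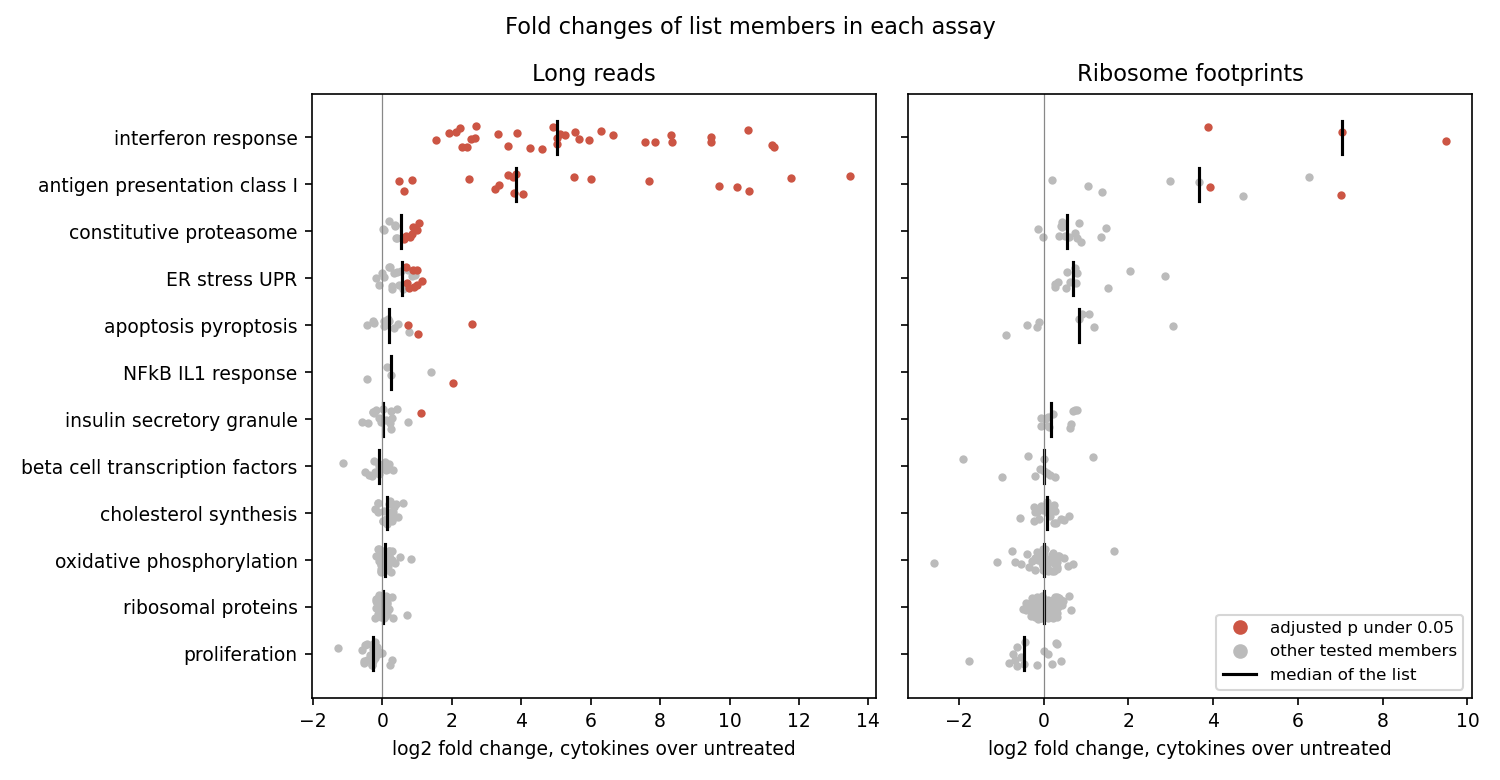
Log2 fold change (cytokine over untreated) of each measured gene of 12 lists, in long reads on the left and footprints on the right, red where the adjusted p is below 0.05, with a bar at the list median. Fitted values of genes with no untreated counts depend on the prior count; the interferon list has medians of 5.02 and 7.03 in the assays.

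Which transcript models changed was asked next. Of 15364 models, 255 rose and 4 fell in edgeR, with 810 at an unadjusted p below 0.05; the block called 1099 and 399, and DESeq2 397 and 3. The count was 170 without untreated replicate 3 and 519 without cytokine replicate 1. The models that rose belong to 95 genes, all of which also rose as a sum, and 38 of these had 2 or more such models. Those with the smallest p were models of PSMB10 (ENST00000358514.9, log2 7.25, SE 0.41), PSME2 (ENST00000216802.10, 4.13, SE 0.25), IRF1 (a one-exon model, 6.86, SE 0.41), PLAAT4 (a model lacking part of a known one, with 0 untreated reads and 444, 543 and 873 after cytokines) and PSMB8 (ENST00000374882.7, with 0, 1 and 0 untreated reads and 181, 262 and 365 after cytokines). The 4 that fell were 3 models of NT5DC2 (adjusted p = 0.021, 0.035 and 0.044) and 1 of NKX6-3 (log2 -1.13, SE 0.23, adjusted p = 0.038). By class, 73 known models, 84 that lack part of a known model, 44 unspliced or genomic ones, 42 with known splice sites in other combinations and 12 with unannotated splice sites rose. With the block 568 of 5401 known models rose and 52 fell, whereas 136 of 4156 genomic models rose and 200 fell.

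A shift between RNA forms of one gene, apart from its total, passed the test in WARS1. Among its 2 known models of 11 exons, WARS1-204 (ENST00000392882.7) made up 5.6% ± 4.9 of reads in untreated and 95.2% ± 0.5 in cytokine-treated cells (mean ± SD, n = 3 each), with WARS1-202 (ENST00000355338.6) taking the rest. The reads were 1 of 13, 2 of 22 and 0 of 11 in untreated libraries (exact 95% intervals 0.2 to 36.0%, 1.1 to 29.2% and 0.0 to 28.5%) and 309 of 323, 794 of 835 and 961 of 1015 in cytokine libraries (92.8 to 97.6%, 93.4 to 96.5% and 93.1 to 96.0%). Of all WARS1 reads, WARS1-204 held 1.2% ± 1.4 and 24.9% ± 12.7, and WARS1-202 18.2% ± 8.7 and 1.3% ± 0.7. Of 3255 genes with 2 or more models, WARS1 was the only gene called (adjusted p = 0.00015; 6.1e-19 with the block), with 8 at an unadjusted p below 0.05. The count was 0 without untreated replicate 2 and without cytokine replicate 3, and 3 without cytokine replicate 1. The block called 23 genes, among which SLC25A22, a mitochondrial glutamate carrier, CD24, CYP51A1, an enzyme of cholesterol synthesis, and IL18BP, the binding protein of interleukin 18, had the smallest p after WARS1. In SLC25A22 the 10-exon known model went from 3.1% ± 2.2 to 23.1% ± 11.4 of reads, and in CD24 the 2-exon model from 28.6% ± 13.6 to 43.6% ± 17.0. Reads of one exon alone made up 45.8%, 34.2% and 42.2% of untreated and 42.5%, 32.2% and 35.6% of cytokine libraries, lower after cytokines in all 3 pairs. The gains of multi-exon models in SLC25A22 and CD24 go the same way. With the one-exon share as a covariate and no block, WARS1, IL18BP (adjusted p = 0.019) and TALONG000054228 were called. SLC25A22, CD24 and CYP51A1 were not called in that fit.

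**Figure D3:**
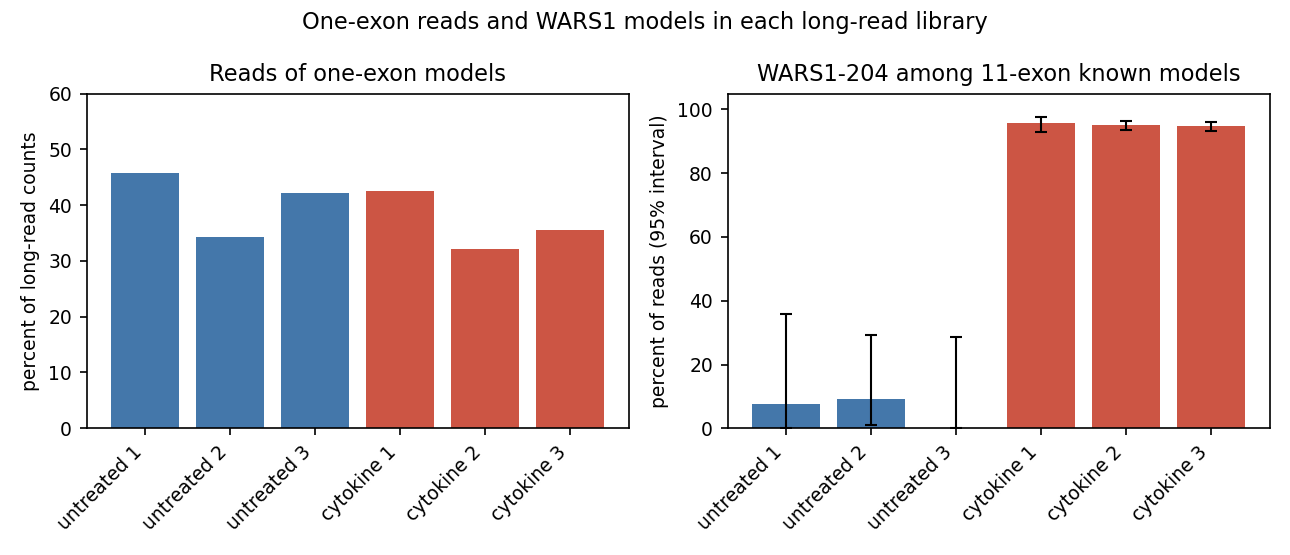
Left, percent of each library's long reads on one-exon models, by replicate and condition; right, percent of WARS1-204 among reads of the 11-exon known WARS1 models with exact 95% intervals. WARS1-204 lies between 0.0% and 9.1% in untreated and between 94.7% and 95.7% in cytokine libraries.

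How ribosome occupancy differs was asked with footprints summed per gene. WARS1 went from 170, 50 and 40 counts in untreated to 28074, 3665 and 3715 in cytokine replicates (log2 7.03, SE 0.43, adjusted p = 0.0061). TAPBP, which holds the peptide transporter to class I molecules, had log2 7.01 (SE 0.50, adjusted p = 0.0078), and IFI30, a thiol reductase of lysosomes, 5.99 (SE 0.66). PLSCR1, a membrane protein induced by interferon, had 4.57 (SE 0.50), CDH1, E-cadherin, 4.53 (SE 0.45), PSME1, a proteasome activator subunit, 3.92 (SE 0.44), and LAP3, a leucine aminopeptidase, 3.87 (SE 0.40). The calls of these 7 ended without untreated replicate 2, untreated replicate 3 or cytokine replicate 2 (lowest and highest adjusted p 0.053 and 0.40). With 1 count per library at positions missing from a table these folds shrank to 3.77 (WARS1), 3.71 (TAPBP), 2.93 (IFI30), 2.29 (PLSCR1), 2.93 (CDH1), 3.41 (PSME1) and 2.89 (LAP3).

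Of 2658 genes tested with footprints 9 rose and 0 fell in edgeR, with 219 at an unadjusted p below 0.05; OPTN, an autophagy receptor chosen after its values were seen, had 2.79 (SE 0.33). DESeq2 called 45 higher and 19 lower, and the replicate block 162 and 107, with all 9 among them. The count was 0 without untreated replicate 2, untreated replicate 3 or cytokine replicate 2. It was 15 without untreated replicate 1 or cytokine replicate 3, and 35 without cytokine replicate 1. Untreated replicate 1 and cytokine replicate 3 are the only libraries of their flow cell. Leaving out either gives the other a flow-cell term of its own. Both fits therefore estimate the change from the same libraries, those of the other flow cell. With 1 count at missing positions 0 genes were called (133 at an unadjusted p below 0.05), and 151 with the block. Untreated and cytokine replicate 1 stood apart from the other 4 libraries: log2 counts per position correlated at 0.909 between them, at 0.736 to 0.77 among the others, and at 0.227 to 0.317 across. A term for that pair in place of the flow cell gave 187 higher and 150 lower genes, and leaving the pair out gave 89 and 47.

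All 3 measured interferon genes, of 66 in the list, had more footprints (3 adjusted over the list alone), WARS1 and LAP3 among them. Of 9 class I genes 2 rose, TAPBP and PSME1, with 8 adjusted over the list alone, 8 with the block and a median log2 of 3.66. The class I list had adjusted p = 1.2e-15, and adjusted p = 0.051 with an estimated correlation. HLA-E had 6.26 (SE 0.86, adjusted p = 0.070; 4.7e-06 with the block, below 0.0085 without untreated replicate 1, cytokine replicate 1 or cytokine replicate 3, and 3.4e-18 by DESeq2). With 1 count per library at missing positions HLA-E had 2.77, CD74 2.703, CD47 1.81 and PDIA4 1.58. CD47 had 2.90 (adjusted p = 0.13; 0.00052 with the block, 0.0099 without cytokine replicate 1); of these 2 checkpoint genes 0 were called in edgeR and 2 in DESeq2, 2 adjusted over the list alone. CD74 had 5.13 (adjusted p = 0.18; 5.1e-06 with the block, 0.015 without cytokine replicate 1), and of 2 class II genes 0 were called in edgeR, 1 in DESeq2 and 1 adjusted over the list alone. Of 14 proteasome genes 0 were called by edgeR or DESeq2 and 0 adjusted over the list alone, with 3 at an unadjusted p below 0.05 and 6 higher with the block; the list had adjusted p = 0.00047, and adjusted p = 0.23 with an estimated correlation. Of 12 ER stress genes 0 were called by edgeR and 1 by DESeq2 (1 adjusted over the list alone, 2 at an unadjusted p below 0.05, 7 higher with the block), led by PDIA4, a disulfide isomerase, with 2.03 (adjusted p = 0.096; 0.00012 with the block, 0.019 without cytokine replicate 1). That list also had adjusted p = 0.00047, and adjusted p = 0.36 with an estimated correlation, and lost its call without untreated replicate 1 (0.115) or cytokine replicate 3 (0.121). By fry with the flow-cell term only the class I list of these was called (adjusted p = 0.0043). By fry with the block the class I, proteasome and ER stress lists had adjusted p = 0.0034, 0.012 and 0.0034.

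In beta-cell genes no footprint change passed. INS had 45330 ± 7359 and 43730 ± 13880 CPM of footprints (log2 -0.06, SE 0.34, adjusted p = 1.00), and CHGA 45040 ± 3581 and 70410 ± 13560 (0.64, SE 0.27, adjusted p = 0.61; 0.0056 with the block). Called by edgeR, by DESeq2 and adjusted over the list alone were 0 of 12 granule genes (4 higher with the block, and a list adjusted p of 0.046 with it, but 0.65 at an estimated correlation), 0 of 10 stimulus-secretion genes and 0 of 6 autoantigens, with 0 at an unadjusted p below 0.05 in each, and 0 of 11 beta-cell transcription factors with 1. Of the other islet cell genes 0 of 3 were called by either tool (1 lower adjusted over the list alone, 1 at an unadjusted p below 0.05): GCG had -1.97 (SE 0.58, adjusted p = 0.44; 0.0062 with the block), and -1.21 with 1 count at missing positions. KRT19, the single exocrine and ductal marker measured, had 0.82 (adjusted p = 0.52; 0.0049 with the block, and called adjusted over the list alone); DESeq2 called 0 of 1. Of 9 apoptosis genes 0 were called by edgeR and 1 by DESeq2 (2 adjusted over the list alone, 2 at an unadjusted p below 0.05), led by TNFSF10 with 3.05 (adjusted p = 0.23; 3.0e-05 with the block, 0.016 without cytokine replicate 1; 2.51 with 1 count at missing positions).

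Footprints on housekeeping lists had medians between -0.07 and 0.09 on the log2 scale. Called by edgeR and by DESeq2 were 0 of 74 ribosomal protein genes, 0 of 21 cholesterol genes, 0 of 20 splicing regulators, 0 of 8 immediate early genes and 0 of 9 loading references, with 0 adjusted over the list alone and 0 at an unadjusted p below 0.05 in each. Of 32 translation factors and 45 oxidative phosphorylation genes edgeR called 0 and DESeq2 1 each (1 lower each adjusted over the list alone; 1 and 3 at an unadjusted p below 0.05): EIF4EBP2, which holds back cap-dependent initiation, had -2.33 (SE 0.36, adjusted p = 0.096; 0.00038 with the block, 0.049 without cytokine replicate 1), and UQCRFS1, the iron-sulfur subunit of complex III, -2.59 (SE 0.37, adjusted p = 0.077; 0.0034 with the block, 0.033 without cytokine replicate 1). With 1 count at missing positions these were -1.26 and -2.17. Of 16 proliferation genes 0 were called by either tool or adjusted over the list alone, 1 had an unadjusted p below 0.05, and 2 were lower with the block, which gave the list adjusted p = 0.037 against 0.088 without it (0.43 and 0.36 at an estimated correlation). No NF-κB, mitochondrial genome or mesenchymal, endothelial and immune gene had a named footprint transcript past the filter.

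Which start sites differ was tested at 60622 positions listed in both conditions. edgeR called 0, with 510 at an unadjusted p below 0.05, and DESeq2 160; the replicate block called 908 higher and 65 lower. With the block, 430 higher positions lay in coding sequences, 96 of the coding positions called being annotated starts, 204 in 5′ UTRs and 266 on transcripts with no annotated coding sequence. On transcripts with a gene name 211 positions were higher and 9 lower, in 51 genes. The annotated start of WARS1, at position 620 of ENST00000355338 and 139 of ENST00000392882, had log2 5.35 (adjusted p = 1.0 with the flow-cell term and 5.9e-12 with the block), and a CTG codon 46 nt upstream of it in the 5′ UTR 4.80 (3.3e-11 with the block). Annotated starts of PSME1 (4.03; 7.6e-11 with the block), PSME2 (3.21; 2.3e-08) and CDH1 (3.87; 6.5e-08) followed the same direction. After positions with the same counts and codons were merged, 11138 passed the filter, of which edgeR called 0 (68 at an unadjusted p below 0.05) and the block 131 higher and 16 lower. Leaving out any library left the count at 0 with the flow-cell term.

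Where footprints lie along transcripts was compared without pairing the replicates, and no class of positions passed. Annotated start codons held 5.87% ± 3.86 of counts in untreated and 5.70% ± 2.89 in cytokine libraries (n = 3 each, exact permutation p = 0.9, adjusted p = 1.0), a difference of -6.08 points within one flow cell (1 library per condition) and 2.78 within the other (2 each). Transcripts with no annotated coding sequence held 64.2% ± 14.2 and 67.2% ± 7.29 (exact permutation p = 0.9), and 5′ UTR positions on a CTG codon 1.30% ± 0.58 and 1.36% ± 0.37 (exact permutation p = 0.9). All 16 classes compared gave exact permutation p values of 0.5 or more; the smallest that 3 against 3 allows is 0.1. Within replicate pairs 1 to 3 some classes moved one way, a pattern seen in the values and not tested: coding footprints in frame by 2.64, 1.43 and 1.31 points, those in the next frame by -1.42, -0.91 and -0.75, 5′ UTR positions on GTG by 0.077, 0.077 and 0.103, and positions on TTG by -0.95, -7.85 and -3.94. Footprints in the other frame (-1.22, -0.52 and -0.56) and in 3′ UTRs (-0.60, -0.033 and -0.053) were also lower in each pair. Both replicate 1 libraries differed from the rest: annotated starts held 10.3% and 9.02% against 3.40% to 4.24%, and coding footprints in frame 74.7% and 77.3% against 60.3% to 62.2%. Positions on TTG differed most, with 2.59% and 1.65% in the replicate 1 libraries against 26.1% to 33.9% in the others. Of the peaks marked by the authors, TTG positions made up 1.63% in untreated and 1.91% in cytokine-treated cells. The authors marked 49390 peaks in untreated and 50020 in cytokine-treated cells, with 28829 in both (40.8% of either). For annotated starts 4732 of 6280 and 6465 were shared (59.1% of either). At the INS start codon of each listed transcript, footprints came to 612 ± 135 and 588 ± 284 RPM, scaled to all listed counts of a library. The CPM of INS as a gene is scaled to counts on named transcripts alone. It also sums INS transcripts that carry the same footprints. The RPM of the start codon therefore cannot be read as a share of the gene's CPM.

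**Figure D4:**
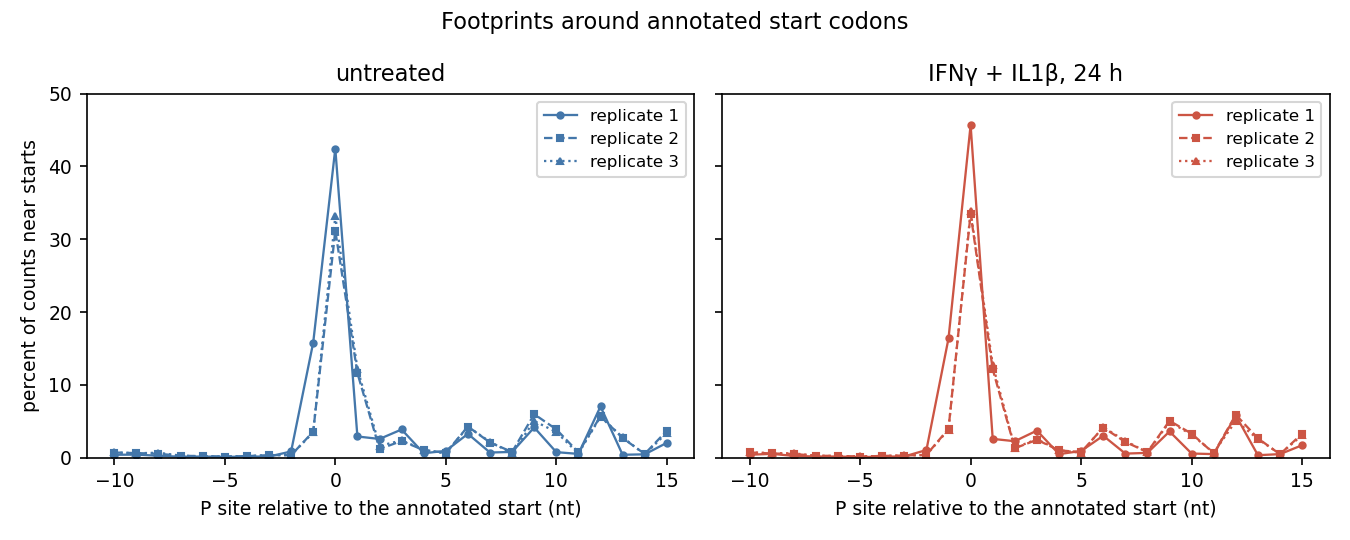
Percent of each library's footprints near annotated starts, by distance of the P site from the start codon in nt, for 3 untreated and 3 cytokine libraries. The peak at 0 holds 42.4% and 45.7% in the replicate 1 libraries and 31.2% to 33.8% in the others, whose share at position 1 is 11.6% to 12.8% against 2.93% and 2.6%.

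Whether ribosome occupancy changed beyond the RNA was asked with the ratio of footprints to long reads. Footprints rose more than RNA in genes with few untreated footprints: FIS1, a mitochondrial fission factor (log2 ratio change 4.23, SE 0.73), TAPBP (3.65, SE 0.49), LSR, a lipoprotein receptor (3.32, SE 0.57), and MAF, a transcription factor (2.15, SE 0.36). UQCRFS1 (-2.57, SE 0.26, adjusted p = 0.0030), PGP (-2.32, SE 0.34), EIF4EBP2 (-2.09, SE 0.27) and FGD5-AS1 (-1.91, SE 0.28) had fewer footprints for their RNA. Of 2646 genes edgeR called 7 higher and 4 lower, with 175 at an unadjusted p below 0.05. The block called 62 and 47, and DESeq2 24 and 23. With 1 count per library at missing positions UQCRFS1 alone kept its call (-2.18, SE 0.30, adjusted p = 0.049), while TAPBP went to 0.39, FIS1 to 1.91, MAF to 1.04 and LSR to 2.49. The count was 1 without long-read untreated replicate 1 or 3 or long-read cytokine replicate 2 or 3, and 2 without long-read untreated replicate 2. It was 6 without long-read cytokine replicate 1 and 5 without footprint untreated replicate 2. Without footprint untreated replicate 1, cytokine replicate 1 and cytokine replicate 3 it was 71, 75 and 78. The fits with 71 and 78 calls take the footprint change from the same libraries, because of the flow-cell term. Class I genes were the only list called of 16 (1 of 9 genes higher, 2 adjusted over the list alone, median 0.53, adjusted p = 0.0021, and adjusted p = 0.22 with an estimated correlation; fry 0.070). Among lists too small for that test or not called, 2 of 3 interferon genes had a higher ratio, and EIF4EBP2 and UQCRFS1 made up the 1 lower gene of 32 translation factors and of 45 oxidative phosphorylation genes.

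Genes with more RNA also had more footprints. All 9 genes called with footprints were among the 89 called higher in long reads of 2648 tested in both assays, where 0.302 would overlap by chance (Fisher's exact test, p = 3.7e-14). With the block 113 were higher in both (16.3 by chance) and 17 lower in both (3.76 by chance), and 0 were called in opposite directions in either analysis. Across genes, which are not independent replicates, log2 fold changes of the assays correlated at Pearson 0.590 and Spearman 0.338. Spearman was 0.825 over the 94 genes called in either assay, a selection that raises it. Over all genes it was 0.288, 0.291 and 0.264 without long-read untreated replicate 2, untreated replicate 3 and cytokine replicate 1, and 0.257, 0.241 and 0.249 without footprint untreated replicate 1, cytokine replicate 1 and cytokine replicate 3.

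**Figure D5:**
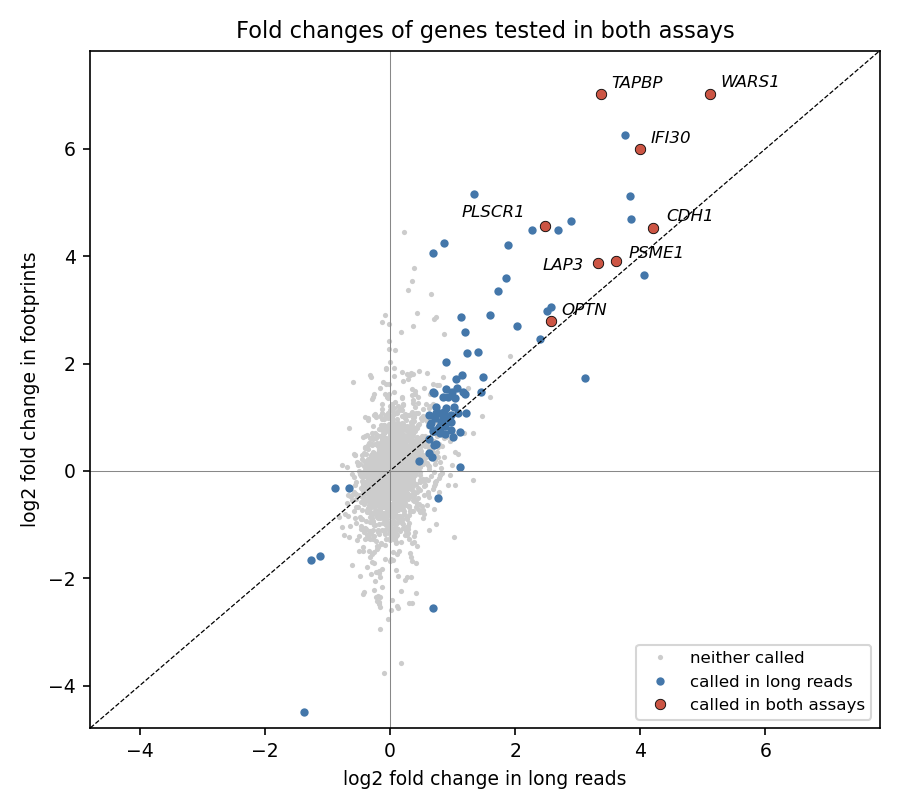
Log2 fold change in footprints (vertical axis) against long reads (horizontal axis) for genes tested in both assays and reported here, with a dashed line of equal change and names at 8 genes called in both. WARS1 lies at 5.11 and 7.03.

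Some RNAs were seen in one condition alone. With at least 3 counts in every library of one condition and 0 in all of the other, 117 transcript models and 34 genes were seen in cytokine-treated and 0 in untreated cells alone. Each of the other 9 ways to divide the libraries gave 0 of either. Thinning all libraries to the smallest total gave 121 models. Besides TAP1, PLAAT4 and UBD these genes include IFIT3, ISG15 and BST2, antiviral genes with 261, 121 and 117 counts, and NLRC5, the activator of class I transcription, with 77.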

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

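The tests of exchanged column names, of the one-exon share and of WARS1 usage were chosen after the results were seen; the P-site shift, the listing minimum and the splits of the libraries were chosen before. Footprints on transcripts without a gene name were outside the comparisons of the report, and they carry a signal: with the replicate block 1154 of 20123 such transcripts rose after cytokines and 834 fell, against 96 and 0 with the flow-cell term. Transcripts of one gene share footprints, so these are not 1154 separate genes.

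In footprints, untreated and cytokine replicate 1 resemble each other by position and differ from the other 4 libraries. A P site placed at another fixed distance in that pair would raise its correlation with the others at some shift. The best of all shifts from -6 to 6 nt gave 0.37 over 120612 positions, against 0.265 over 248409 with no shift. These sets of positions differ, so the values are not directly comparable. Near annotated starts the largest share lay at 0 in the pair (42.4% and 45.7%) and in the others (31.2% to 33.8%). At -1 the pair held 15.8% and 16.4% against 3.49% to 3.98%, and at 1 it held 2.93% and 2.6% against 11.6% to 12.8%. The shared peak at 0 argues against another fixed distance as the whole cause. The labels put untreated replicate 1 and cytokine replicate 3 on one flow cell and give their samples names of one stem, apart from those of the other 4, while cytokine replicate 1 correlates at 0.909 with untreated replicate 1. Exchanged column names of cytokine replicates 1 and 3 are a candidate explanation, which the sample names go with, and a difference in preparation between replicates is another; no measured value decides between them. No biological explanation was tested, and a term for the pair in place of the flow cell gave 337 footprint gene calls.

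For the footprint to long-read ratio, positions below the listing minimum were counted as 0. With 1 count per library at such positions 1 of the 11 calls stayed, UQCRFS1, and the minimum may account for changes such as WARS1 (1.96, then -1.30) and TAPBP (3.65, then 0.39), whereas LSR (3.32, then 2.49, adjusted p = 0.059, and 0.0023 with the replicate block) and PIP4K2C (2.69, then 2.11, adjusted p = 0.27) kept most of their fold. Of 100 drawn splits of the libraries 15 gave as many calls, the real one with 11 included and the highest other with 117, so chance is not excluded. Of the 14 others 8 kept the real split in 1 assay. With the replicate block only the 32 splits that part every same-numbered pair were run. The real count was 109, the highest had 546 (the real long-read split with footprints reversed), and splits real in neither assay had 0.

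With the replicate block 568 known models rose and 52 fell in cytokine libraries, whereas 136 genomic models rose and 200 fell; without it 44 genomic models rose and 1 fell. The median change of the one-exon share over 1167 genes not called was below 0 in 3 of 3 pairs (-2.77, -2.42 and -8.13 points). This restates the smaller one-exon share of whole cytokine libraries and cannot tell its cause; a biological change in RNA integrity or processing stays open and was not tested. That share does not explain WARS1, where the leading 11-exon model moved by 89.6 points against another model of the same exon number.

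The 6 libraries of an assay allow 10 splits, too few for a share under 0.05. For long-read genes 1 of 10 splits gave as many calls (real 200, highest other 0), and for footprint genes 1 of 10 (real 9, highest other 0). For long-read transcripts 2 of 10 did (real 259, highest other 3522) and for usage 2 of 10 (real 1, highest other 1773). That other split sets untreated 1, untreated 3 and cytokine 1 apart, the libraries with the largest one-exon shares. It points to a structure of the samples. With the replicate block only the 4 splits that part every same-numbered pair were run. Among them the real counts were 1498 and 23, and the highest other 0. The split with 3522 and 1773 calls keeps both replicate 1 libraries on one side. It was therefore not run with the block, and these counts say nothing about it. For footprint sites all 10 of 10 splits gave 0 calls in edgeR, with 510 sites at an unadjusted p below 0.05 in the real split and 160 called by DESeq2.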

How the results depend on the processing

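Chosen after the data were seen were the one-exon covariate, the term for the replicate 1 pair, leaving out both replicate 1 libraries, merged positions, 1 transcript per gene, the most counted transcript, positions listed in both tables, missing positions as 0 with missing transcripts or at 1 count, the block with annotated starts or the most abundant position, and, for the correlation of the assays, the block and leaving out each library. No result reversed. Of long-read fold changes of 79 named genes, 1077 comparisons with an alternative kept their call, 72 gained and 34 lost it; for 61 named genes in footprints these were 1366, 168 and 50. Except where stated, the cause was not tested.

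The replicate block gave 735 long-read genes, 1498 transcripts, 23 usage genes, 269 footprint genes, 973 sites, 109 ratio genes and 5 footprint lists. Leaving out both replicate 1 libraries gave 366 long-read genes, 696 transcripts, 136 footprint genes and 483 sites. The run-name prefix gave 521 long-read genes and 723 transcripts, and the one-exon share as covariate 399, 670 and 3 usage genes. Usage with no filter beyond 1 count gave 2. DESeq2 gave 400 transcripts, 64 footprint genes, 160 sites and 47 ratio genes. The term for the replicate 1 pair gave 337 footprint genes, 792 sites and 83 ratio genes, and no flow-cell term 18 footprint genes. Merged positions with the block gave 147 sites.

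Footprint genes numbered 0 from annotated starts only (31 with the block), 0 from the most abundant position (54), 149 with missing positions and transcripts as 0 (448), 1 from positions listed in both tables (77), 0 with 1 count at missing positions (151), and 351 from the most counted transcript with the block. In edgeR the counts of 0 had 18, 23 and 133 genes at an unadjusted p below 0.05 for starts, the top position and 1 count. Ratio genes numbered 1 with 1 count at missing positions (5 with the block) and 0 from positions listed in both tables (2; 13 at an unadjusted p below 0.05). With an estimated correlation 2 long-read lists, 0 footprint lists and 0 ratio lists were called, and by fry 4, 1 and 0. Over genes called in either assay the correlation of the assays was 0.8254, by selection.

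Leaving out each library gave 137 to 325 long-read genes (325 without cytokine replicate 1), 170 to 519 transcripts (170 without untreated replicate 3, 519 without cytokine replicate 1), 0 to 3 usage genes (0 without untreated replicate 2 or cytokine replicate 3, 3 without cytokine replicate 1), 7 to 8 long-read lists, 0 to 35 footprint genes (0 without untreated replicate 2 or 3 or cytokine replicate 2, 15 without untreated replicate 1 or cytokine replicate 3, 35 without cytokine replicate 1), 2 to 4 footprint lists, 0 to 0 sites, 1 to 78 ratio genes, correlations of 0.241 to 0.3703 and a change in the start-codon share of -1.837 to 2.05 points. For footprints and the ratio, leaving out untreated replicate 1 or cytokine replicate 3 rests on the same footprint libraries, through the flow-cell term. Other scalings and filters kept the total counts of long-read genes, footprint genes and sites within 1.5 times. The split by direction moved more: library sizes alone gave 158 higher and 23 lower long-read genes, against 189 and 11. Thinning all libraries to the smallest total gave 121 models seen after cytokines alone against 117, and a start-codon difference of -0.184 against -0.175 points; depth was not compared with other limits. In data of the same depth simulated with the dispersion of the flow-cell fit, 3.1% of 2-fold changes were called in footprints. In separate data simulated with the dispersion of the block fit, 61.9% were called. The common dispersion was 0.231 in the flow-cell fit and 0.0329 in the block fit. Neither simulation held a replicate effect, so these values do not measure what blocking gains on the same data.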

Other observations

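Genes in this part were chosen after their values were seen. Beyond the lists, RNA rose for SOCS1, which damps cytokine signalling (log2 6.29, SE 0.36), LGALS3BP (6.54, SE 0.34), IL18BP (6.11, SE 0.29), the metallothionein MT2A (2.94, SE 0.29), NAMPT, an enzyme of NAD synthesis (2.18, SE 0.20), STAT3 (1.55, SE 0.24), CEBPB (1.43, SE 0.21), ADAR, an RNA editing enzyme (1.37, SE 0.14), and KARS1, the lysyl-tRNA synthetase (1.15, SE 0.16). NNMT had no untreated reads and was at least 111-fold higher. The complement genes C4A and C4B, whose reads can be shared, had 2.26 and 2.69. GNG4 (-0.77), TAFA5 (-0.77) and HADH, an enzyme of fatty acid oxidation that restrains insulin release (-0.66), completed the 11 genes that fell. In footprints DANCR had -4.49 (SE 0.72, adjusted p = 0.10; 6.8e-06 with the block).

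Cytokine replicate 1 had few long reads of chemokines and of some other genes while WARS1 rose alike in all pairs. Log2 differences within pairs 1, 2 and 3 were 3.26, 8.97 and 8.92 for UBD, 0.422, 2.68 and 2.31 for NFKBIA, and 1.99, 4.53 and 3.81 for CD74, but 4.92, 5.07 and 5.3 for WARS1. LTB, a lymphotoxin, had 0, 24 and 34 reads in cytokine replicates and 0 in untreated ones (adjusted p = 0.052 with no filter, 1.1e-07 with the block), and CTSS, a cathepsin of class II presentation, 0, 18 and 31 against 0 (adjusted p = 0.058; 6.3e-07 with the block). CCNE2 (log2 -1.29, adjusted p = 0.43; 0.0088 with the block) and NDUFA9 (0.81, adjusted p = 0.26; 0.0012 with the block) passed when cytokine replicate 1 was left out (0.045 and 0.016), and with no other single library left out.

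Among genes with at least 100 footprints listed in one condition alone, 53 were listed for cytokine-treated and 40 for untreated cells. Of the 53, 31 rose in long reads and 19 are in the interferon or class I lists, with TAP1 (3933 counts), IL18BP (3427), IRF1 (3277) and MT2A (2806) first; their median long-read log2 fold change was 2.61 over 52 with a value. Of the 40, 0 were called in long reads by edgeR without the replicate block, and their median was -0.088; with the block ITGAE (log2 -0.94, adjusted p = 0.00037), SLC25A29 (-0.63, 0.0020), SLC16A1 (-0.77, 0.0052) and UNG (-0.58, 0.021) were lower and TFPT (0.68, 0.034) higher. HLA-B had 228, 133 and 136 footprints in cytokine replicates and none listed for untreated cells.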
